A study of Mus musculus with 6 samples.

How the data were processed

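Gene-level read counts of 6 libraries from dissected mouse olfactory epithelium were used, 3 from wild-type mice and 3 from mice hemizygous for 5x21-OR1A1. Per the labels' protocols, poly-A RNA was made into nonstranded TruSeq libraries and read as single-end reads of 100 bp on a HiSeq 4000. The values are raw counts per gene symbol as deposited by the authors, with no normalization. TopHat2 2.1.1 and HTSeq 0.9.1 and the genome build GRCm38.p5 are named in the submitters' processing notes. The annotation release, the counting options and the treatment of reads with several matches are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and receptor genes with near-identical copies may have lost or shared reads.

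All 53686 symbols of the table named a gene and 49627 were found once in a reference annotation of the same build, from which coordinates were taken. Library totals ran from 27506217 to 35804712 counts. Replicates of 1 group differed by far more than counting noise, so no pair was treated as 1 library. Odorant receptors were sorted into 122 class I and 969 class II genes by a range of Olfr numbers fixed before the data were examined; 314 receptor pseudogenes and 14 olfactory Taar genes were kept apart. An alternative from receptor family names, chosen after seeing the data, classed 7 genes differently.

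Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter by group (a minimum count of 10 and a total of 15), the quasi-likelihood fit and test on genotype, and Benjamini-Hochberg adjustment over the 19267 genes kept. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM values are relative to TMM-scaled totals. For 27 gene lists, calls were counted over all genes and adjusted over the list alone, and the lists were tested with camera in limma 3.58.1 on log2 CPM at a preset correlation of 0.01 and with an estimated correlation. Camera adjusted p-values were corrected over the 27 lists, and separately over 4 receptor sets, which were class I, class II, Taar genes and receptor pseudogenes. Fry in limma, which tests whether a list changed without comparing it to other genes, was corrected alike. It was run on the main comparison only. Shares of counts, the ratio of class I to class II and the entropy of receptor counts were compared by two-sided exact permutation tests, which cannot go under p = 0.1 here. Receptor clusters were runs of receptor genes within 1 Mb, with at least 5 tested genes, and 100000 shuffles within class.

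Named genes followed a rule fixed before the data were examined. It takes the 10 largest rises and falls outside the odorant receptors and the 5 largest in each receptor class, among genes past the threshold with a mean of at least 1 CPM and no overlap of groups. It also takes all possible matches of transgene sequence, well studied receptors and tested Taar genes, up to 4 genes with the lowest adjusted p of each other list, and the 3 receptors most abundant in wild-type libraries. Receptor pseudogenes were placed with the receptors for this rule.

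The count tests were tested on simulated data with 200 changed genes at the means, depths and dispersions of this comparison. Among 19043 genes, edgeR recovered 36% of genes changed by 1.5-fold, 70% at 2-fold, 92% at 3-fold and 98% at 4-fold, with 19 false calls among unchanged genes, 11.4% of its calls and more than the 5% the threshold allows. DESeq2 1.42.0 recovered 58, 86, 94 and 100% with 48 false calls among 19267 genes, 22.1% of its calls. The cluster test gave p under 0.05 in 7% of 100 simulations with shuffled receptor values and in 99% with 4 clusters shifted by 1.5 on the log2 scale. The shifted clusters were those with the most tested genes. Values were shuffled across both receptor classes and kept no likeness between neighbouring genes, so these percentages may not hold for the real values. A first form of that check, a single simulated data set with a stricter bound on p, had not been met, and the repeated simulations took its place.

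Alternatives covered other scalings, among them scaling to mature neuron markers, DESeq2 and limma-voom, no filter and a stricter filter (1 CPM in 3 libraries), the replicate number as a block, sex as a covariate, an adjusted p under 0.01, and leaving out each library. A scan of neighbouring genes along chromosomes used windows of 10 genes and 10000 shuffles of gene order, and was added after seeing the data. It left out odorant, trace amine and vomeronasal receptor genes, receptor pseudogenes and genes without a place on an autosome or the X chromosome, which kept 17816 genes, or 17761 without antigen-receptor segments. Nothing was aligned to the sequence of the transgene, which is not used here.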

Results

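Poly-A RNA was sequenced from dissected main olfactory epithelium of C57BL/6J mice, the nasal tissue that holds the olfactory sensory neurons together with their progenitors, supporting cells and glands. The 6 libraries fell into 2 groups of 3, wild-type mice and mice hemizygous for the 5x21-OR1A1 transgene, which carries the human odorant receptor OR1A1. The wild-type libraries held 30908191, 35804712 and 30177731 counts, and the transgenic libraries 35423577, 29725688 and 27506217. The series title places the comparison in the question of how a neuron chooses its receptor when 1 receptor transgene is highly represented. The comparison made here is therefore between genotypes, first over the mouse's own receptor genes and then over the other genes of the tissue. The labels give the libraries as separate replicates without naming the animals, so p-values measure the spread between these libraries.

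The mouse's own odorant receptors were lower in transgenic tissue, class I receptors most of all. Of 109 class I genes tested, 78 were lower and 0 higher, with a median log2 fold change of -1.68. Of 768 class II genes, 167 were lower and 16 higher, with a median of -0.64. Of 12 trace amine-associated receptor (Taar) genes, which olfactory neurons also express, 4 were lower and 0 higher, with a median of -1.06. Camera placed class II, class I and Taar genes below all other genes at the preset correlation (adjusted p = 6.23e-16, 1.25e-60 and 2.30e-09), and the adjusted p was 0.158, 0.0714 and 0.0714 with an estimated correlation. Fry, which does not compare a set with other genes, called these sets down (fry adjusted p = 0.0354, 0.00387 and 0.00579). Adjusted over the list alone, 95 class I genes were lower and 1 higher, 316 class II genes were lower and 56 higher, and 8 Taar genes were lower. Mature neuron markers were lower in the same libraries, at 2.29% ± 0.322 of all counts in wild-type and 1.40% ± 0.0655 in transgenic tissue (SD, n = 3 each; exact permutation test, p = 0.1). With counts scaled to those markers, the log2 fold change of the median gene was 0.71, and the class II calls became 192 higher and 151 lower, while 76 class I genes were called lower. The class II count was 111 without wild-type library 2 and 55, 57 and 58 without transgenic libraries 1, 2 and 3, and the Taar count was 1, 2 and 2 without these transgenic libraries.

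The summed receptor counts gave the same order. Class I genes took 0.107% ± 0.0261 of counts in wild-type and 0.0383% ± 0.00262 in transgenic libraries, a log2 ratio of -1.45 (SE 0.21). Class II genes took 0.323% ± 0.0510 and 0.204% ± 0.0147, a log2 ratio of -0.66 (SE 0.15), and Taar genes 0.00361% ± 0.000837 and 0.00162% ± 0.0000951, a log2 ratio of -1.13 (SE 0.20). All 3 transgenic libraries lay below all 3 wild-type libraries in each class, which gives p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 allows. Per count of mature neuron markers, class II differed by 0.04 (SE 0.053), class I by -0.75 (SE 0.14) and Taar genes by -0.43 (SE 0.13) on the log2 scale. The marker counts were summed, so Omp, at 11518 CPM in wild-type tissue, weighed most. Single tested markers ranged from -0.81 (Gng13) to -0.06 (Slc17a6) with a median of -0.66, so the class II value depends on the markers used. The log2 ratio of class I to class II counts differed by -0.79 between transgenic and wild-type libraries (SE 0.16; two-sided exact permutation test, p = 0.1). Among all tested odorant receptors, camera ranked class I genes below class II genes with p = 1.85e-12 at a preset correlation of 0.01 and p = 0.238 with an estimated correlation.

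**Figure D1:**
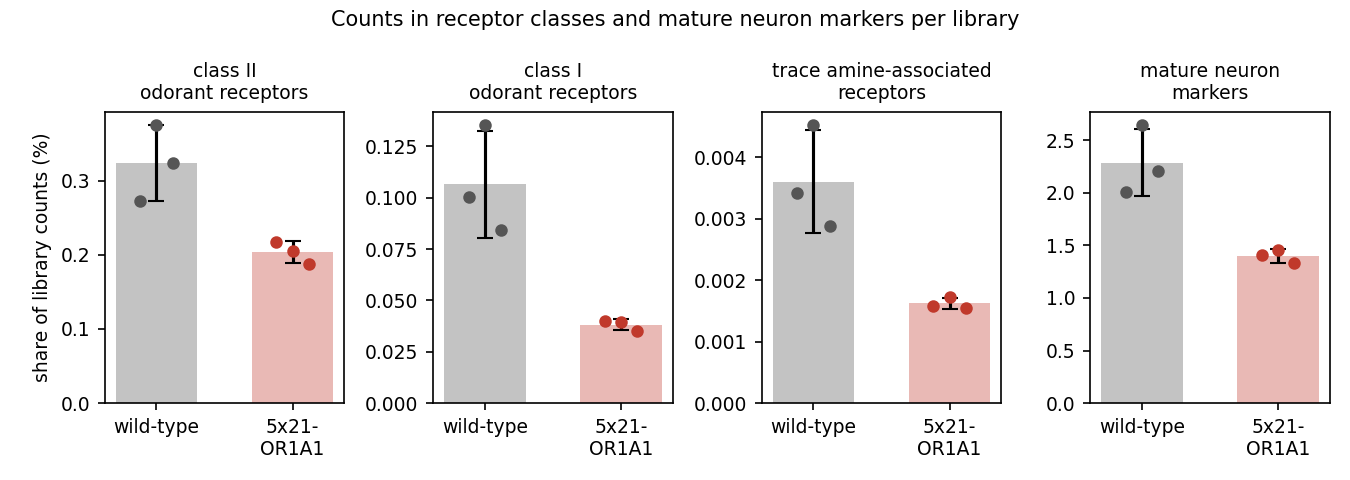
Share of each library's counts, in percent, taken by class II receptors, class I receptors, Taar genes and mature neuron markers; points are libraries, bars are means and error bars are SD (n = 3 per group). Class I receptors lie between 0.0353 and 0.0401% in transgenic libraries and between 0.0843 and 0.135% in wild-type libraries.

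Among class I genes the largest falls were those of Olfr618 (log2 fold change -3.69, SE 0.22, edgeR adjusted p = 0.000913), Olfr560 (-3.37), Olfr657 (-3.27), Olfr678 (-3.08) and Olfr684 (-2.72). Olfr618 went from 9.74 ± 2.21 to 0.752 ± 0.0281 CPM (counts scaled to a common library total; SD, n = 3). Among class II genes Olfr351 (-3.38), Olfr355 (-3.25), Olfr1024 (-3.21), Olfr922 (-3.19) and Olfr517 (-2.82) fell most. The largest rises in class II were Olfr944 (2.46), Olfr1535 (2.18), Olfr1295 (1.95), Olfr299 (1.69) and Olfr172 (1.66), all from under 1 CPM in wild-type tissue. The receptors most abundant in wild-type tissue, Olfr969 and Olfr640, fell by 1.97 and 1.54 on the log2 scale, and Olfr598 fell from 31.9 ± 8.23 CPM in wild-type tissue (SD, n = 3; edgeR adjusted p = 0.0231). Of the Taar genes, Taar7a (-2.45), Taar7d (-1.84), Taar2 (-1.73) and Taar3 (-1.43) fell. Reads of near-identical receptor genes may have been split or dropped in counting, so values of single members of such groups are uncertain. Olfr560, at 102751818 to 102759366 on chromosome 7, lies within the span of Olfr78 on the same strand, which had a value of 0.72. Reads of overlapping genes may also have been shared or dropped, so both values are uncertain.

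**Figure D2:**
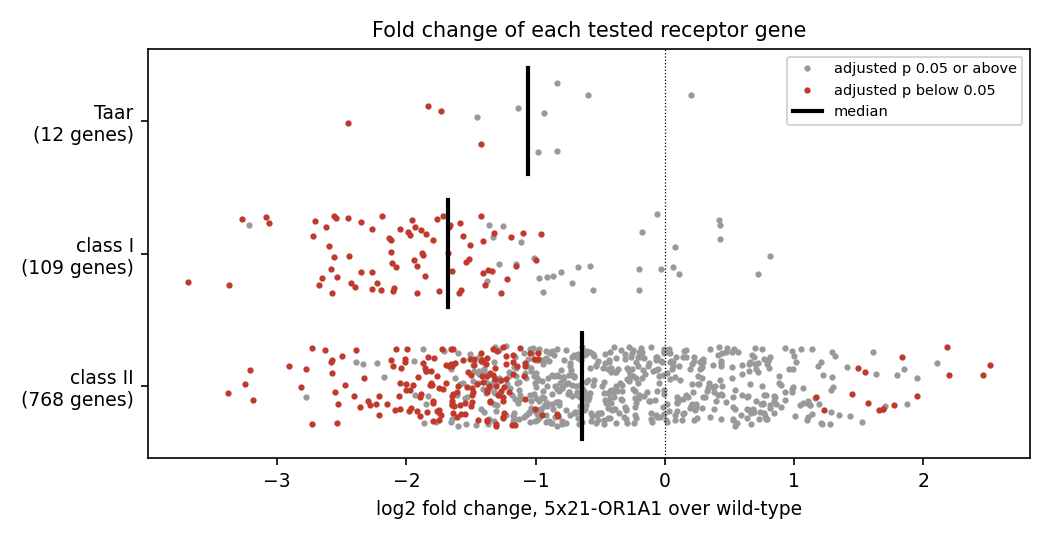
Log2 fold change, 5x21-OR1A1 over wild-type, of each tested class II, class I and Taar gene; red points passed an edgeR adjusted p of 0.05 and black bars mark medians. The medians are -0.64 for class II, -1.68 for class I and -1.06 for Taar genes; vertical scatter within a row carries no value.

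The table holds no row named for the transgene or its construct, so OR1A1 itself is not analysed here. Of 6 genes fixed beforehand as possible matches of transgene sequence 1 rose and 2 fell. Olfr151, the M71 receptor, rose from 0.0548 ± 0.0492 to 7.89 ± 2.25 CPM (log2 fold change 7.14, SE 0.51, edgeR adjusted p = 0.00121), with 3, 0 and 2 counts in wild-type and 205, 294 and 217 in transgenic libraries. Olfr151 lies on chromosome 9 at 37729977 to 37731104 on the minus strand of GRCm38 and is annotated as a polymorphic pseudogene, so it stands outside the class II counts. Olfr160, a close relative on the same chromosome at 37708964 to 37716250, fell by 1.58 on the log2 scale, and Olfr16 fell by 1.61. Mapt, which encodes tau, had a value of -0.14, Olfr43 of 0.18 and Olfr403 of -0.88, with edgeR adjusted p of 0.488, 0.813 and 0.158. Of 11 well studied receptors tested, Olfr151 rose and 4 fell, Olfr16, Olfr160, Olfr545 (-1.97) and Olfr73 (-1.24). Values that did not pass were 0.72 for Olfr78, 0.11 for Olfr558, 0.66 for Olfr15, 0.44 for Olfr17, 0.98 for Olfr2 and 1.85 for Olfr1509, and Olfr1507 and Olfr1508 had too few counts to test.

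Receptor change was also compared between genomic clusters. Of 27 clusters with at least 5 tested genes, 21 had a median below 0. The cluster on chromosome 7 at 102476579 to 105369355 held 109 class I genes among 111 tested and had a median log2 fold change of -1.68, with 103 genes lower. The 8 tested genes on chromosome 1 at 92475925 to 92623412 had the highest median, 0.83, with 0 lower. The variance of cluster medians was 0.331 against a mean of 0.159 when genes were shuffled among clusters within class (permutation test over genes, p = 0.0013), and genes are not independent replicates. With whole chromosomes in place of clusters the permutation p was 0.300, and another division of the libraries into 3 and 3 gave a variance of 0.378. The variance was 0.202 without wild-type library 2 (p = 0.0217 in the same permutation test over genes) and 0.767 without wild-type library 3. Shannon entropy of receptor counts was 9.06 ± 0.164 bits in wild-type and 9.22 ± 0.00430 bits in transgenic libraries at matched receptor depth (SD, n = 3 each; two-sided exact permutation test, p = 0.4). Wild-type library 3, at 9.25 bits, lay above all 3 transgenic libraries, and the difference of 0.155 bits was 0.249 without it and 0.103 without wild-type library 1. At that depth receptor genes with at least 10 counts numbered 735, 727 and 826 in wild-type and 834, 835 and 837 in transgenic libraries (two-sided exact permutation test, p = 0.1).

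Neuronal markers were split by stage. Of 14 mature olfactory sensory neuron markers tested, 5 fell, 0 rose and 9 did not pass, with a median of -0.66; adjusted over the list alone, 13 were lower. Omp, the olfactory marker protein, went from 11518 ± 1581 to 6787 ± 190.5 CPM (SD, n = 3 each; log2 fold change -0.76, SE 0.14, edgeR adjusted p = 0.0305). Gng13, a G protein subunit of olfactory neurons, fell by 0.81, Gfy, a Golgi protein needed for olfactory signalling, by 0.76 and Umodl1 by 0.71. Of 14 immature neuron markers 4 rose, with a median of 0.42 (10 adjusted over the list alone), among them Gap43, a growth cone protein (0.78, SE 0.10), Dpysl3 (0.72), Stmn1 (0.51) and Stmn2 (0.44). Of 16 progenitor markers 7 rose, with a median of 0.55 (14 adjusted over the list alone), among them the neurogenic transcription factors Insm1 (0.97, SE 0.13) and Sox11 (0.74) and the mitotic gene Top2a (0.60). Camera with a preset correlation called these 3 lists, down, up and up, with adjusted p of 1.21e-09, 2.46e-07 and 4.49e-10; with an estimated correlation the adjusted p was 0.807, 0.474 and 0.474. Camera at the preset correlation also called 5 to 8 of the 27 lists in each other division of these libraries into 3 and 3. Fry, which does not compare a list with other genes, called the immature and progenitor lists up (fry adjusted p = 0.0345 and 0.0297). It did not call the mature list, whose direction was down (fry adjusted p = 0.145).

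**Figure D3:**
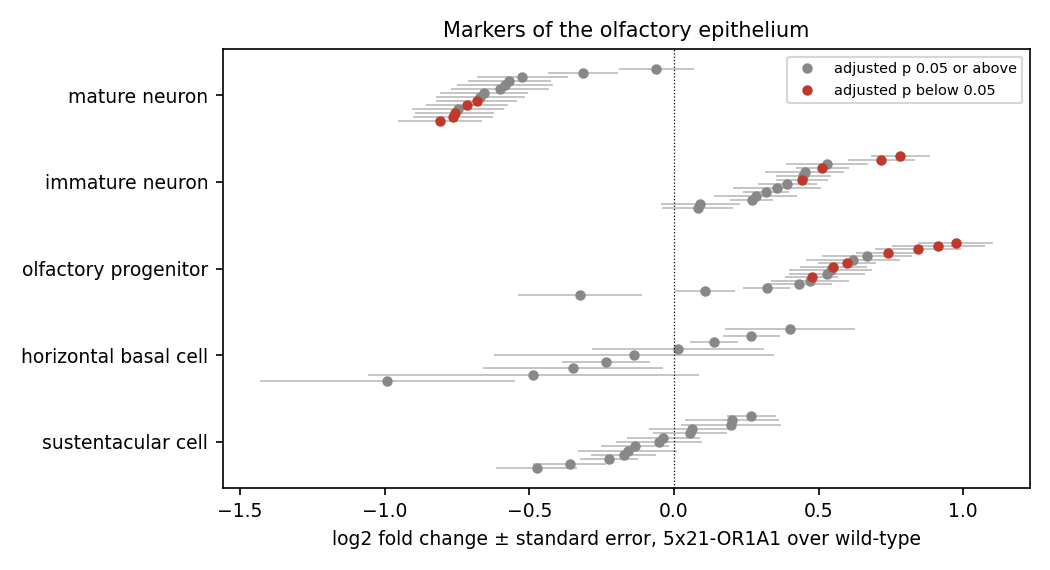
Log2 fold change with its standard error, 5x21-OR1A1 over wild-type, of each tested marker of mature neurons, immature neurons, progenitors, horizontal basal cells and sustentacular cells; red points passed an edgeR adjusted p of 0.05. List medians are -0.66, 0.42, 0.55, -0.14 and -0.05.

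No member of 9 tested horizontal basal cell markers (median -0.14), 13 sustentacular cell markers (-0.05), 18 gland markers (0.23), 11 microvillous cell markers (0.09), 12 respiratory ciliated cell markers (0.17) or 12 glia markers (-0.002) passed the edgeR threshold. The same held for 8 erythrocyte markers (-0.40), 11 muscle, bone and cartilage markers (0.19), 9 vomeronasal and other chemosensory markers (0.11), 5 tested sex chromosome genes (-1.24), 5 ventral zone markers (0.41), 11 heat shock genes (-0.25) and 12 endothelial cell and fibroblast markers (0.28). Camera called the last list up at the preset correlation (adjusted p = 0.0247) and not with an estimated one (adjusted p = 0.853). The preset call was lost with sex as a covariate (adjusted p = 0.0906), with counts scaled to mature neuron markers (0.603), without wild-type library 2 (0.291) and without transgenic library 3 (0.101). Among gland genes Bpifb9b differed widely between libraries, at 136 ± 144 CPM in wild-type and 3457 ± 4675 CPM in transgenic tissue (SD, n = 3). Both sexes were present in both groups by Xist and Ddx3y counts, with 1 female among wild-type and 2 among transgenic libraries. With sex as a covariate 289 genes were called, 64 of them class I genes lower and 95 class II genes lower.

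Few members passed in the lists tied to receptor choice and neuronal activity. Of 28 genes for receptor choice and feedback 1 fell, the transcription factor gene Ebf4 (-0.74, SE 0.11, edgeR adjusted p = 0.0162), with a list median of 0.03. Adcy3, the olfactory adenylyl cyclase (-0.60, edgeR adjusted p = 0.123), Reep1 (-0.63, 0.0581) and Ddit3 (0.40, 0.0829) did not pass. Of 20 unfolded protein response genes 1 rose, Trib3 (1.02, SE 0.09), at 60.9 ± 2.64 CPM in transgenic tissue, with a list median of 0.09. Of 22 activity-dependent and axon guidance genes 1 fell, S100a5 (-0.81), a calcium-binding protein whose expression follows odorant activity, with a list median of -0.04. Of 16 immediate early genes 1 fell, Ier2 (-0.83), with a median of -0.76; camera called the list down at the preset correlation (adjusted p = 0.0161), and the adjusted p was 0.853 with an estimated correlation. The preset call was lost without wild-type library 2 (adjusted p = 0.319) and without transgenic libraries 2 and 3 (0.0645 and 0.156). Egr1, a member of this list, was at 7.21, 133 and 33.6 CPM in the wild-type libraries. Of 6 dorsal zone markers 1 fell, Nqo1 (-1.18, SE 0.15), an enzyme of dorsal olfactory neurons, from 553 ± 123 to 243 ± 6.96 CPM; Acsm4, of dorsal supporting cells, had a value of -0.45 (edgeR adjusted p = 0.143) and the list a median of 0.07. Of 21 immune cell markers 1 rose, Jchain, of antibody-secreting cells (1.52; list median 0.10). Ifit1 (-0.50) was among the genes that fell in the list of 15 interferon response genes (list median 0.01). Of 10 tested olfactory bulb and brain markers, a list not only of neuronal genes, Slc1a2 (-0.84) and Eomes (-0.90) fell (list median -0.24).

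Over all genes, 19267 were tested by edgeR and 523 passed an adjusted p of 0.05, 100 higher and 423 lower in transgenic tissue, 239 of them neither odorant or trace amine receptors nor receptor pseudogenes. In 1 simulated data set with 200 changed genes, 11.4% of edgeR calls at this threshold were false. Of these 239 genes, 78 were higher and 161 lower. Outside the odorant receptors the largest rises at 1 CPM or more with no overlap of the groups were those of an immunoglobulin kappa variable segment (1.94), Jchain (1.52), 2900060N12Rik (1.36), Aldh1l2, a mitochondrial folate enzyme (1.34), Knl1, a kinetochore protein (1.29), 5430403N17Rik (1.15), Gtf3c3, a subunit of transcription factor IIIC (1.08, SE 0.08), Trib3 (1.02), Rab3c and Insm1 (0.97). The largest falls were those of Taar7a, Cyp2c44 (-2.04), Taar7d, 4930516K23Rik (-1.82), Taar2, 4931428L18Rik (-1.62), Pth2, a neuropeptide gene (-1.51, SE 0.15), Taar3, Hpcal4 (-1.25) and Tmem59l (-1.22). Of these, 4930516K23Rik lies on chromosome 7 at 104053600 to 104061445, within the class I receptor cluster, whose median was -1.68. Chance alone leaves 10% of genes with no overlap between 3 and 3 libraries. The total was 313 without wild-type library 2 and 155, 175 and 150 without transgenic libraries 1, 2 and 3; outside the receptors it was 108 and 154 without wild-type libraries 2 and 3 and 29, 44 and 26 without the transgenic ones. DESeq2 called 1195 genes, and with counts scaled to mature neuron markers 14707 genes were called higher and 255 lower, around a median shift of 0.71.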

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

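Alternatives for the chromosome 1 run and the receptor class from family names were chosen after seeing the data; the others were fixed before the data were examined. The share of class II counts, -0.66 on the log2 scale, was 0.0416 per count of mature neuron markers, which removes the fall of their summed counts. The class I share was then -0.75 and the Taar share -0.43. Without the 10 most abundant of the 14 Taar genes, which leaves only the least abundant, the Taar share was -0.77. By the median of gene fold changes the class difference was -1.04. The cause of these shifts was not tested. Leaving out 1 library gave class II shares of -0.78 to -0.55, class I shares of -1.61 to -1.27, Taar shares of -1.28 to -0.95 and class differences of -0.95 to -0.71, all in the main direction.

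Scaling to mature neuron markers moved the median of all genes by 0.71 and gave 14962 changed genes, 14707 higher and 255 lower, 14498 changed outside the receptors, 192 class II genes higher, 8 lists and a chromosome 1 median of -0.15. It turned Mapt to 0.56, Ermn to 0.49, Sox10 to 0.58, Ifit1 to 0.20, Col9a1 to 0.48, Cdhr1 to 0.42, Snap25 to 0.43, Car2 to 0.54, Dnaja1 to 0.47 and Plxna3 to 0.31. DESeq2 gave 1195 changed genes, 297 higher and 898 lower, 795 outside the receptors, 34 class II genes higher and 8 Taar genes lower; why was not tested. Without the count filter 163 genes were higher, 379 changed outside the receptors and 28 class II genes higher. With sex as a covariate the counts were 289 changed, 52 higher, 237 lower, 95 class II lower, 8 class II higher and 105 outside the receptors. At an adjusted p under 0.01 they were 154, 12, 142, 62, 2 and 24, with 2 Taar genes and 3 lists. Clusters taken as whole chromosomes gave a variance of 0.138.

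Replicate numbers did not pair the libraries: same-numbered libraries deviated from their group means with correlations of -0.33, 0.07 and -0.17. With the replicate number as a block the count of changed genes was 377, with 54 higher, 9 class II genes higher and 159 changed outside the receptors; the class I count was 75, the class II lower count 116, the Taar count 3 and the list count 5. Leaving out 1 library, which leaves fewer samples, gave 150 to 626 changed genes, 14 to 154 higher, 136 to 472 lower, 55 to 186 class II lower, 1 to 33 class II higher, 55 to 81 class I lower, 1 to 5 Taar lower, 26 to 329 outside the receptors and 3 to 8 lists (3 without transgenic library 3, 8 without wild-type library 3). Of the named genes tested, 38, 36 and 39 lost their call without transgenic libraries 1, 2 and 3, and 11, 25 and 17 without wild-type libraries 1, 2 and 3. DESeq2 yields no camera value, and the choice of denominator cancels in the class difference, so neither was run.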

Other observations

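Tests in this part were chosen after the results were seen, except for some values planned beforehand. These were edgeR values of single genes, the class I to class II difference and class I counts per count of mature markers. The counts and the cluster variance over other divisions of the libraries were also planned. The use of these values to weigh causes of the class difference, and the divisions for the chromosome 1 run, came after. In a scan of 10-gene windows along the autosomes and the X chromosome, over 17816 genes and with odorant, trace amine and vomeronasal receptor genes left out, the window furthest from 0 lay on chromosome 12 at 114288152 to 115208591, held 10 immunoglobulin segments and had a median of 1.99, with 1 segment past the edgeR threshold. Vomeronasal receptor genes had a positive value in 82 of 96 tested, with a median of 0.47 and 1 gene called. Igkc, the kappa constant region, was at 94.8 ± 22.9 CPM in wild-type and 247 ± 97.8 CPM in transgenic tissue (SD, n = 3; edgeR adjusted p = 0.0624).

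With antigen-receptor segments also left out after that first scan, 17761 genes remained and the window furthest from 0 lay on chromosome 1. From Cavin2 to Dnah7a, at 51289126 to 53706784, all 21 tested genes were lower, 15 of them past the edgeR threshold, with a median of -0.86 and quartiles of -0.95 and -0.73. They include Hibch (-0.86) and Ormdl1 (-0.99). Among the 17761 genes the window furthest from 0 elsewhere had a median 0.791 in size, and the furthest in any shuffle 0.843 in size. The run was taken to end at the last called gene on each side. Tmeff2 before it had a value of -1.15, and Stk17b, Hecw2 and Ccdc150 after it had values of -0.72, -0.41 and -0.18, none of them past the edgeR threshold. Gtf3c3, the next gene tested, rose by 1.08, and Pgap1 next to it had a value of 0.72 (edgeR adjusted p = 0.0829), while Ankrd44 beyond them was at 0.09. Elsewhere on chromosome 1, 16 of the 1086 genes in the scan were called.

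The tables argue against random placement of changed genes along the genome as a source of the chromosome 1 run: in a permutation test no shuffle of gene order held a window as far from 0 (p = 0.0001, the smallest that the shuffles can give). Loss of 1 of 2 copies of the interval, for example where a hemizygous transgene inserted, and a stretch of another strain's DNA linked to the transgene cannot be told apart here. Of 16 genes with at least 2 CPM in wild-type, 13 (81.2%) lay within 2 standard errors of a log2 change of -1, but 14 lay above it, with a median of -0.86 and quartiles of -0.94 and -0.75. The run was found by its lower genes, so neither these values nor its 21 of 21 lower genes decide between the 2, and a regulatory effect over the interval was not tested. The median over the run was 0.857 in size in the real division of the libraries and at most 0.360 in the others, and 10 divisions are too few for a share under 0.05. The other divisions mix the genotypes in each group, which would shrink the median of a genotype difference.

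Olfr151 was higher in all 3 transgenic libraries. Reads of Olfr160 counted on Olfr151 would keep the ratio of both genes, and the log2 ratio differed between groups by 8.83 (SE 1.14). Reads of the transgene that match Olfr151 may account for its 716 counts in transgenic libraries, but the counts carry no position along the gene and the construct sequence is not used here, so this cannot be told apart from expression of the gene itself.

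Class I receptors fell further than class II receptors. An even loss of mature neurons as the whole cause would leave class I counts per count of mature markers alike. These differed by -0.75 (SE 0.14, two-sided exact permutation test, p = 0.1). A loss mainly of neurons that express class I receptors would lower this ratio too, so the values do not speak to it. Less dorsal tissue in the dissection, where class I receptors are expressed, stays open: Acsm4, of dorsal supporting cells, was lower against the other sustentacular markers by a difference of -0.39 (SE 0.13), beside -0.79 (SE 0.16) for class I against class II. Acsm4 is a single gene, with a log2 fold change of -0.45. The tested sustentacular markers themselves ranged from -0.48 (Sult1c1) to 0.27 (Fmo2), so Acsm4 cannot decide. Nqo1, of dorsal olfactory neurons, fell by more, with a log2 fold change of -1.18 (SE 0.15), while the 6 dorsal zone markers had a median of 0.07. Nqo1 would be lower with less dorsal tissue and with fewer dorsal neurons alone, so it cannot decide either. A biological effect of genotype, the difference named by the design, stays open and was not tested.

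Over the 10 divisions of the 6 libraries into 3 and 3, the real one called 523 genes and the highest other 36, the division of female from male libraries. It called 167 class II, 78 class I and 4 Taar genes against 0 in each other division, each count being reached in 1 division, the real one. Gene lists called by camera numbered 5 in the real division and up to 8 in others, with 10 of 10 divisions at 5 or more. The variance of cluster medians was 0.331 and at most 0.378 in others, with 2 divisions as large. With 10 divisions no share can be under 0.05. Each other division puts both genotypes in each group, so a genotype difference would add to the spread within groups and lower its gene counts. Low gene counts there are thus no separate support for the real division.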
